A study of Mus musculus with 3 samples.

How the data were processed

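RNA-seq was measured in 3 libraries from the initial segment and caput of the epididymis of 14-week-old mice labelled as Ovch2 knockouts. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a stranded TruSeq mRNA kit, which selects polyadenylated RNA. The authors deposited 1 table of the whole series, which per the file headers holds normalized FPKM values (fragments scaled by transcript length and library total) for each gene and library. Per the submitters' processing notes, the tools were TopHat2 2.1.1 and Cufflinks 2.2.1 and the genome build was mm10. The gene annotation, the strand setting, any filter and the scaling behind the word normalized are not given in the sources used here.

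FPKM divides by length, so a short gene with few fragments can take a very large value, and 1297 of 24346 genes are annotated as shorter than 200 bases. Near-identical family members share reads, and a gene-level value does not tell which exons were read. The kit keeps strand, but the setting used for quantification is unknown, so reads of overlapping antisense genes cannot be ruled out. A value of 0 can be a failed estimate. Rpl26, a ribosomal protein gene, was listed at 0 in replicates 1 and 3. Ndufs5, a complex I gene, stood at 6.73, 32.0 and 0.00188 FPKM. Among 100 genes with symbols of the Rpl or Rps type, 4 were listed at 0 in replicate 1 and 3 in replicate 3. That symbol pattern also takes in pseudogenes such as Rps15a-ps6, so some of these zeros may be genes that were not expressed. Zeros are therefore called listed at 0, and no fold of a named gene is given against them. Counts of genes apart by 2-fold or 8-fold are on the FPKM + 1 scale and include genes listed at 0, whose number is given.

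The table's columns were assigned to samples by their names. Gene identifiers were matched to the RefSeq annotation of GRCm38.p6, which has the mm10 coordinates, and 24260 of 24346 matched. Coordinates are 1-based. Values were analysed as log2(FPKM + 1). Because FPKM values are not counts, no count model was used, and because the labels give 1 group, no group test was made.

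Depth was examined through low values. Among genes under 0.5 FPKM in both libraries of a pair, the ratios of values gathered at small whole-number ratios of a common step. The shares were 56.9% for replicates 1 and 2, 63.6% for replicates 3 and 2, and 57.3% for replicates 1 and 3. The tolerance was 0.02 on the log2 scale. Of random ratios spread evenly on that scale, 16.2% did so. No step was fitted to the random ratios, so 16.2% can understate the rate by chance. The steps gave the relative depths but not absolute ones, so no counting interval or floor was computed.

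The gene lists (29 lists of symbols and 9 families defined by symbol), the tests and the rule for naming genes were fixed before the data were examined. The rule named Ovch2, 2 to 4 examples per list (the members of highest and lowest mean and any listed at 0 while others were not), the 20 genes of highest mean, and the 10 genes with a mean of at least 5 FPKM and the widest range. Other list members given as examples were chosen after their values were seen. Values of some list members are not reported here. For each list and library, the median log2(FPKM + 1) was ranked among 10000 random lists of equal size. Each gene's deviation from its 3-library mean was also taken, and the list's median deviation was compared, two-sided, with 10000 random lists matched on mean expression in 10 bins. The p-values, of which 0.0002 was the smallest possible, were adjusted by Benjamini-Hochberg over 38 lists and 3 libraries, 114 pairs, with a threshold of 0.05. The difference between the initial segment and caput medians was tested with an exact sign-flip test. Correlations were computed across genes.

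The deviation test was tested on simulated data with 24346 genes and 10 simulations, at a spread of 0.25 on the log2 scale. It called 90% of 20 pairs lowered by 0.5, 100% of 20 pairs lowered by 1 or 2, and 0.362% of 828 unchanged pairs. The simulated spread was equal for all genes and independent between them. Genes of a real list can vary together and differ in spread, so these rates do not carry over to the lists tested here.

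Alternatives were leaving out each replicate, median-of-ratios scaling, rescaling to a fixed total, a pseudocount of 0.1, a mean of at least 1 FPKM for list members, other detection thresholds and a mean of at least 5 FPKM for variable genes. Leaving out genes under 200 bases was added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.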

Results

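RNA was measured in the initial segment and caput, the proximal regions of the epididymis in which sperm leaving the testis begin to mature. The tissue came from 14-week-old mice labelled as Ovch2 knockouts. The labels gave 1 group of 3 libraries, named here replicates 1, 2 and 3. Ovch2 encodes ovochymase 2, a serine protease that the initial segment secretes into the lumen under the lumicrine pathway. In that pathway NELL2, made by germ cells, reaches the receptor ROS1 on the epididymal epithelium through the duct, and OVCH2 is needed for the processing of ADAM3 on sperm. The design asks which epididymal programs and cell types the tissue labelled as knockout expressed, and how alike the libraries were. No control tissue was analysed here, so no value below is a difference from wild-type tissue and no test between genotypes was possible. The labels do not say whether the libraries came from separate animals, so the spread between them can be technical. Percentiles and p-values from random gene lists describe these libraries and not a population of animals.

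The deposited table held 24346 genes with an FPKM value in each library. Totals were 729695 FPKM in replicate 1, 745294 in replicate 2 and 814000 in replicate 3. Absolute depth is unknown, because the table holds no counts. Steps between low values put the relative depth of replicate 1 at 1.22 times that of replicate 2 and 1.40 times that of replicate 3. Genes at or above 1 FPKM numbered 12945 ± 106 (SD, n = 3). The 10 most abundant genes took 18.3 ± 0.841% of the total (SD, n = 3).

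Ovch2 itself (NCBI gene 244199, mm10 chromosome 7 from 107781544 to 107801179, minus strand) was read in all 3 libraries labelled Ovch2 knockout. Its level was 4.50 FPKM in replicate 1, 80.2 FPKM in replicate 2 and 77.2 FPKM in replicate 3, or 54.0 ± 42.9 FPKM (SD, n = 3). The mean was 78.7 FPKM without replicate 1. These coordinates are those of RefSeq. The strand was taken from the GENCODE annotation, which ends the gene at 107801208 and gives it 1 transcript of 16 exons. Which exons were deleted is not given in the sources used here, and a gene-level FPKM does not tell which part of the transcript the reads came from. Ovch2 RNA was therefore no check of the genotype labels in either direction.

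The libraries were compared before any values were averaged. Across 24346 genes, Pearson's r on the log2(FPKM + 1) scale was 0.965 between replicates 1 and 2, 0.969 between replicates 1 and 3, and 0.989 between replicates 2 and 3. Spearman's rho was 0.958, 0.962 and 0.978 for these pairs. Genes are not independent replicates, so no p is given. Of 13073 genes with a mean of at least 1 FPKM, 532 lay at least 2-fold below both other libraries in replicate 1, 99 in replicate 2 and 20 in replicate 3, of which 65, 3 and 6 were listed at 0 there. Those at least 2-fold above both other libraries numbered 169, 31 and 41, of which 4, 4 and 7 were listed at 0 in both others. Between the highest and lowest library, 1409 genes varied at least 2-fold, against 230 without replicate 1 and 884 without replicate 2. Folds are on the FPKM + 1 scale, which understates those of low genes.

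Gpx5, a glutathione peroxidase of the caput lumen, was highest at 31337 ± 5039 FPKM (SD, n = 3). Spag11b, an epididymal beta-defensin-like gene, stood at 16483 ± 2130 FPKM. The 20 most abundant genes were ranked by their mean over libraries that differed widely, and among them were the lipocalins Lcn5, Lcn8 and Lcn2, the beta-defensins Defb25, Defb18, Defb20, Defb47, Defb42 and Defb15, and the cystatin Cst11. Of these, Lcn8 (8.58 FPKM), Defb25 (16.8 FPKM), Cst11 (150 FPKM) and Defb47 (267 FPKM) were far less abundant in replicate 1. Clu, encoding the luminal chaperone clusterin, stood at 17809, 5841 and 9312 FPKM in replicates 1, 2 and 3. The uncharacterised gene 9230104L09Rik, which lies beside the cystatins on chromosome 2, stood at 6.31, 6745 and 6337 FPKM. The remaining genes of the 20 were Crip1 (7727 ± 849 FPKM), Eef1a1 (4940 ± 368 FPKM), Tmsb4x (4272 ± 385 FPKM), Rps27rt (3875 ± 639 FPKM), the microRNA gene Mir703 and the ribosomal RNA precursor Rn45s. Mir703 is only 109 bases long, and its 20075 ± 2382 FPKM (SD, n = 3) is read with caution for that reason. Rn45s stood at 324, 3816 and 8568 FPKM.

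Genes of the initial segment program were low in replicate 1 and high in the other 2 libraries. Of the 17 listed genes, 14 were lowest in replicate 1 and 11 lay at least 2-fold below both other libraries there. Adam28, an ADAM protease gene, stood at 0.190, 915 and 718 FPKM in replicates 1, 2 and 3. Rnase10, an RNase A family gene needed for ADAM3 maturation, stood at 2.58, 3077 and 2708 FPKM. Cst11, the member of highest mean, stood at 150, 7263 and 7124 FPKM, and Spry4, the lowest, at 0.901, 3.28 and 2.62 FPKM. The other 3 genes were highest in replicate 1: Rnase9 at 2479, 364 and 1686 FPKM, Rnase13 at 917, 303 and 458 FPKM, and Ggt1, a glutathione-degrading enzyme gene, at 252, 72.6 and 112 FPKM. The median of the list was 2.26, 7.56 and 7.18 on the log2(FPKM + 1) scale. It ranked at the 78.6th percentile of random lists in replicate 1 and at the 100th in the other libraries.

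Each gene was also set against its own mean over the 3 libraries. A list's deviation is the median of these differences over its genes, with 10000 random lists matched on expression as the reference. The initial segment list deviated by -2.57 in replicate 1, 1.40 in replicate 2 and 1.21 in replicate 3 on the log2 scale (permutation over random lists, adjusted p = 0.0012 for each). The 3 deviations of a gene sum to 0, so calls in different libraries are linked. With 2 libraries the deviations are equal and opposite, so a list above the mean in both must change sign in at least 1 or lie at 0, and such a change shows no instability. Without replicate 1, the initial segment list deviated by 0.09 in replicate 2 and -0.09 in replicate 3, and without replicate 2 it deviated by 1.91 in replicate 3. Over all 38 lists, 39 of 114 list and library pairs passed an adjusted p of 0.05, 13 in each library. In replicate 1, 10 of the 13 lay below the mean. Without replicate 1, 12 pairs in the 2 remaining libraries passed. With 2 libraries fewer pairs exist and the 2 calls of a list mirror each other, so the 12 and the 39 are not directly comparable.

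**Figure D1:**
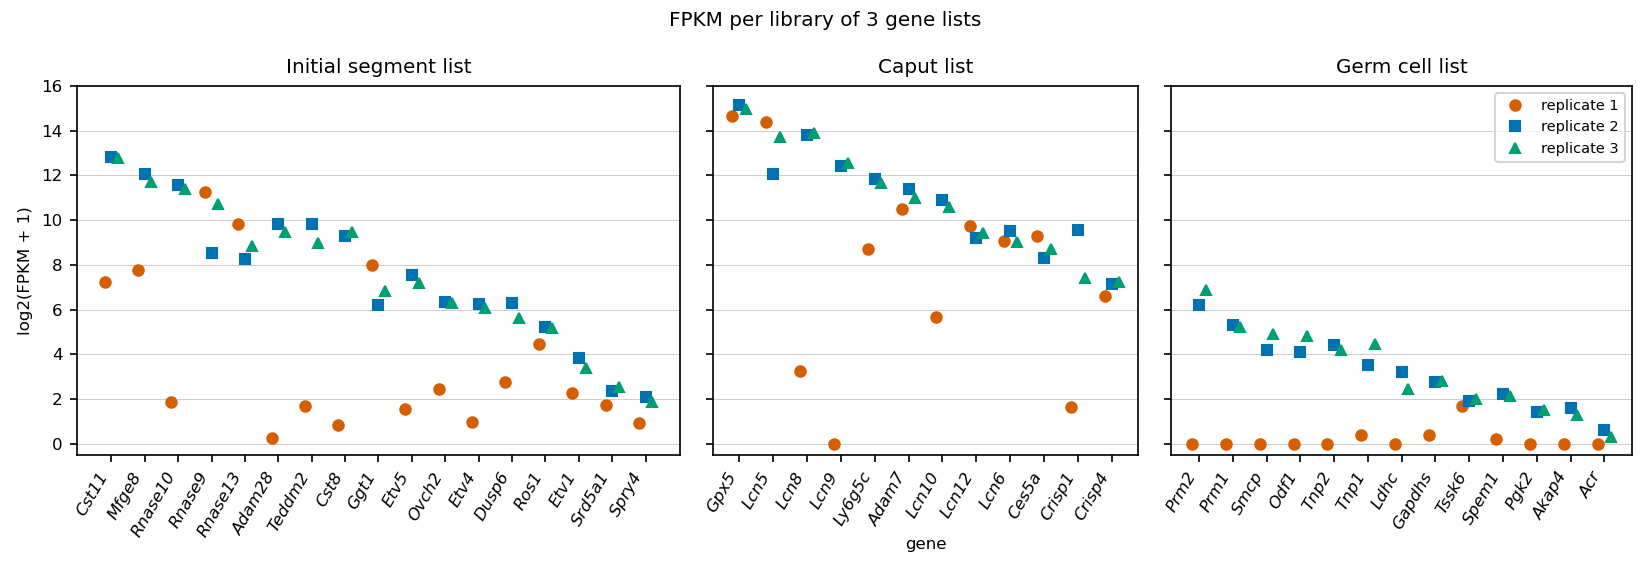
FPKM on the log2(FPKM + 1) scale (vertical axis) of each gene (horizontal axis) of the initial segment, caput and germ cell lists, with 1 point per library and genes ordered by mean level within each panel; a point at 0 is a gene listed at 0. In replicate 1, 14 of the 17 initial segment genes, 8 of the 12 caput genes and all 13 germ cell genes were lowest.

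The lumicrine and ERK pathway list covered the receptor, the kinase cascade and its transcriptional outputs. Of its 15 genes in the table, 12 were lowest in replicate 1 and 5 lay at least 2-fold below both other libraries there. The ETS factor genes Etv4 (0.960, 75.9 and 66.1 FPKM) and Etv5 (1.94, 188 and 144 FPKM) and the ERK phosphatase gene Dusp6 (5.72, 77.1 and 48.5 FPKM) were among them. The kinase gene Map2k2 stood at 60.4, 62.5 and 66.6 FPKM. Ros1, the receptor gene, stood at 21.1, 36.6 and 34.8 FPKM. Nell2 was at 0.151 and 0.131 FPKM in replicates 1 and 2 and listed at 0 in replicate 3. The list deviated by -0.35, 0.17 and 0.20 (permutation, adjusted p = 0.0012, 0.0087 and 0.0038). Ros1, Dusp6, Spry4, Etv1, Etv4 and Etv5 also belong to the initial segment list, so the 2 results are not independent. Without replicate 1 its deviation was 0.09 in replicate 2 and -0.09 in replicate 3. It deviated by 0.11 in replicate 3 with each library rescaled to the same sum and by 0.29 in replicate 2 with a pseudocount of 0.1.

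Caput genes differed between libraries gene by gene. Lcn8 stood at 8.58, 14252 and 15342 FPKM, Lcn10 at 49.1, 1898 and 1513 FPKM, and Lcn9 was listed at 0 in replicate 1 against 5415 and 6106 FPKM. Their neighbour Lcn5 had 21673, 4289.8 and 13581 FPKM, and Lcn6 had 542, 724 and 515 FPKM. In mm10, Lcn8 (25653118 to 25656217), Lcn5 (25657932 to 25662230), Lcn6 (25676638 to 25681608) and Lcn10 (25682726 to 25686081) follow each other on chromosome 2, with Lcn9 (25823088 to 25825546) farther along. Crisp1, a sperm-coating protein gene, stood at 2.07, 758 and 171 FPKM, and Crisp4, the member of lowest mean, at 97.3, 139 and 148 FPKM. Of the 12 genes, 8 were lowest in replicate 1 and 5 lay at least 2-fold below both other libraries there. The list's median was 8.90, 11.14 and 10.78, at the 100th percentile of random lists in every library, and its deviation was -0.41, 0.37 and 0.28 (permutation, adjusted p = 0.0021, 0.0012 and 0.0012). Without replicate 1 the deviations in replicates 2 and 3 were 0.02 and -0.02, without replicate 2 that in replicate 1 was -0.27, and with each library rescaled to the same sum that in replicate 3 was 0.19.

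The median of the initial segment list lay below that of the caput list in each library. The difference, initial segment minus caput, was -6.64 in replicate 1, -3.58 in replicate 2 and -3.60 in replicate 3 on the log2 scale, a mean of -4.60 ± 1.76 (SD, n = 3). A two-sided exact sign-flip test gave p = 0.25, the smallest p that 3 libraries allow. The 2 lists hold different genes, so the sign depends on which genes were listed and does not rank the regional programs.

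The secreted protein families of the epididymis followed more than one pattern. The lipocalin and cystatin results are not independent of the region lists, since Lcn5, Lcn6, Lcn8, Lcn9, Lcn10 and Lcn12 are caput list genes and Cst8 and Cst11 initial segment list genes. In the lipocalin family (10 genes), 4 genes lay at least 2-fold below both other libraries in replicate 1, and Lcn2, encoding a siderophore-binding lipocalin, stood at 2006, 7266 and 6421 FPKM. Its deviations were -0.44, 0.43 and 0.27 (permutation, adjusted p = 0.0012, 0.0012 and 0.0021), and those in replicates 2 and 3 were 0 without replicate 1. The family deviated by -0.24 in replicate 1 without replicate 2, and over members with a mean of at least 1 FPKM by -1.18, 0.68 and 0.50. With a pseudocount of 0.1 the deviation of all 10 genes in replicate 3 was 0.41. In the cystatin family (9 genes), 8 were lowest in replicate 1. Cst8 stood at 0.781, 626 and 712 FPKM and Cst12 at 0.576, 5676 and 5135 FPKM, whereas Cst3, a broadly expressed cystatin, stood at 1069, 1167 and 1456 FPKM. Cst11, Cst12 and Cst8 lie together on mm10 chromosome 2 between 148768618 and 148805596. The cystatin deviations were -0.54, 0.15 and 0.40 (permutation, adjusted p = 0.0012, 0.026 and 0.0012), and -0.08 in replicate 2 and 0.08 in replicate 3 without replicate 1. Most members were near 0, and over the 4 with a mean of at least 1 FPKM the deviations were -4.71, 2.32 and 2.39. Over all 9 members the deviations without replicate 3 were -0.32 in replicate 1 and 0.32 in replicate 2. With a pseudocount of 0.1 those of all 9 were -1.66, 0.71 and 0.96.

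Of the 43 beta-defensin genes, which encode antimicrobial and sperm-coating peptides, 32 had a mean of at least 1 FPKM. In this family 14 genes lay at least 2-fold below both other libraries in replicate 2 and 7 did so in replicate 1. Defb39 stood at 3790, 396 and 2943 FPKM and Defb23 at 105, 2.46 and 93.5 FPKM. In contrast, Defb25 stood at 16.8, 12487 and 14292 FPKM and Defb48 at 15.5, 6197 and 5197 FPKM. The family deviated by 0.22, -0.17 and 0.27 (permutation, adjusted p = 0.0012 for each), and by 0 in replicates 1 and 3 without replicate 2. Over the 32 members with a mean of at least 1 FPKM it deviated by 0.51, -0.61 and 0.42. The whole family of 43 deviated by 0.35 in replicate 1 and -0.56 in replicate 2 with a pseudocount of 0.1. In replicate 3 it deviated by 0.13 without replicate 1 and by 0.18 with each library rescaled to the same sum, and in replicate 2 by -0.31 without replicate 3. The family holds near-identical copies, between which read assignment is uncertain.

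Among the other families, the WAP four-disulfide inhibitors deviated by 0.05, -0.14 and 0.07, past the threshold in replicate 2 alone (permutation, adjusted p = 0.0156), and by -0.02 there without replicate 1 and -0.06 without replicate 3, neither past it. With a pseudocount of 0.1 the deviation there was still -0.14 but no longer past the threshold, and over members of at least 1 FPKM it was -0.21. Wfdc10, the highest, stood at 3735 ± 349 FPKM (SD, n = 3). The Kazal inhibitors, RNase A genes, serpins, trypsin-like proteases and ADAM genes passed the threshold in no library, with deviations between -0.05 and 0.03. Of 63 serpins and 84 trypsin-like proteases, 14 each had a mean of at least 1 FPKM, so a median over all members could hardly move. Over members with a mean of at least 1 FPKM, the RNase A genes passed it in replicates 2 and 3 (-0.32 and 0.24), the Kazal inhibitors in replicate 1 (0.45) and the trypsin-like proteases in replicates 1 and 2 (0.23 and -0.15), and the serpins and ADAM genes in none. Single members of these families still differed, such as the Kazal inhibitor gene Spink8 (5879, 1591 and 3705 FPKM) and Serpina1f (493, 70.5 and 191 FPKM). Adam7, an epididymal ADAM gene, stood at 1461, 2691 and 2034 FPKM. The ADAM3 maturation list joins sperm and epididymal factors and shares Rnase10, Ovch2 and Ros1 with the initial segment list, so the results are not independent. It deviated by -0.27, 0.18 and -0.01 (permutation, adjusted p = 0.0012, 0.0038 and 0.942), and by 0.03 in replicate 2 without replicate 1. With a pseudocount of 0.1 it deviated by -0.63 in replicate 1 and 0.46 in replicate 2, and without replicate 2 by -0.15 in replicate 1. Over members of at least 1 FPKM it deviated by -0.49, 0.28 and 0.21, past the threshold in each library. In it Tpst2, a tyrosylprotein sulfotransferase gene, stood at 128, 424 and 433 FPKM, Ace at 454, 140 and 215 FPKM, and Adam3 itself at 0.459, 1.71 and 0.748 FPKM.

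Germ cell transcripts, which reach the epididymis with sperm, were low or listed at 0 in replicate 1. All 13 listed genes were lowest there, and 9 were listed at 0 in that library alone. The protamine genes Prm1 and Prm2, which package sperm chromatin, were listed at 0 in replicate 1, with 38.9 and 36.4 FPKM for Prm1 and 73.4 and 117 FPKM for Prm2 in replicates 2 and 3. Tnp1, a transition protein gene, stood at 0.301, 10.3 and 21.0 FPKM, and Tssk6, a spermatid kinase gene, at 2.22, 2.78 and 3.02 FPKM. The list deviated by -1.88, 0.76 and 0.84 (permutation, adjusted p = 0.0012 for each), and by -0.03 in replicate 2 and 0.03 in replicate 3 without replicate 1. It deviated by -1.22 in replicate 1 without replicate 2, by 1.56 in replicate 2 without replicate 3, and by -3.47, 1.62 and 1.55 with a pseudocount of 0.1. A value of 0 can also be a failed estimate in this table, since Rpl26, a ribosomal protein gene, was listed at 0 in replicates 1 and 3.

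Epithelial cell lists split by type. Clear and narrow cells, which acidify the lumen, were represented by 8 genes, of which 6 were highest in replicate 1. Foxi1, their transcription factor, stood at 84.4, 33.4 and 37.3 FPKM and the proton pump subunit gene Atp6v1g3 at 38.5, 18.5 and 17.5 FPKM. The list deviated by 0.37, -0.16 and -0.24 (permutation, adjusted p = 0.0026, 0.0694 and 0.0026), and by -0.01 in replicate 3 without replicate 1. Over members with a mean of at least 1 FPKM it deviated by 0.62, -0.30 and -0.26, past the threshold in each library. The principal cell list, which shares Lcn8 and Gpx5 with the caput list and so is not independent of it, deviated by -0.26, 0.21 and 0.05 (permutation, adjusted p = 0.0505, 0.036 and 0.947). It deviated by 0.03 in replicate 2 without replicate 1. With a pseudocount of 0.1 the deviation in replicate 2 was still 0.21 but no longer past the threshold. In it Cftr, a chloride channel gene, stood at 2.02, 11.2 and 7.34 FPKM. Basal cell genes passed the threshold in no library (-0.19, 0.01 and 0.00), with Krt5 at 84.8, 48.8 and 52.9 FPKM. Multiciliated cell genes did not pass it either (0.05, -0.06 and 0.04).

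Among stromal and immune lists, smooth muscle deviated by 0.40, -0.11 and -0.30 (permutation, adjusted p = 0.0044, 0.632 and 0.0012), and by -0.07 in replicate 3 without replicate 1. Its contractile genes Acta2 (306, 193 and 178 FPKM) and Myh11 (78.1, 53.4 and 45.4 FPKM) were highest in replicate 1, but the enteric actin gene Actg2 stood at 49.9, 1341 and 1316 FPKM. Macrophage and dendritic cell genes deviated by -0.41, 0.25 and 0.17 (permutation, adjusted p = 0.0026, 0.0033 and 0.0271), with 11 of 12 lowest in replicate 1, and by 0.05 and -0.05 in replicates 2 and 3 without it. In replicate 3 they deviated by 0.30 without replicate 2 and 0.09 with each library rescaled to the same sum. The complement gene C1qa stood at 37.6, 54.1 and 61.6 FPKM and Cd74, of antigen presentation, at 73.7, 112 and 89.7 FPKM. Endothelial genes deviated by -0.49, 0.40 and -0.02 (permutation, adjusted p = 0.0026, 0.0033 and 0.947), and by -0.23 in replicate 1 without replicate 2 and 0.22 in replicate 2 without replicate 1. The adhesion gene Pecam1 stood at 4.43, 12.1 and 7.49 FPKM. The glial list passed in replicate 3 alone (0.32, -0.14 and -0.24, permutation, adjusted p = 0.0583, 0.267 and 0.0392), and lay at -0.07 there without replicate 1. With the 3 members of at least 1 FPKM alone the deviation there was still -0.24 but not past the threshold. The whole glial list lay at -0.47 there with a pseudocount of 0.1. The erythroid list also passed in replicate 3 alone (-0.06, -0.02 and 0.30, permutation, adjusted p = 0.473, 0.925 and 0.0055). Only 2 of its members, Hba-a1 and Alas2, had a mean of at least 1 FPKM. Over these 2 genes the deviation was 1.23 in replicate 3 and -0.97 in replicate 1, both past the threshold. In replicate 3 the whole erythroid list deviated by 0.18 without replicate 2 and 0.51 with a pseudocount of 0.1. Of its haemoglobin genes, Hba-a1 stood at 8.46, 31.5 and 119 FPKM, whereas its near-identical copy Hba-a2 (0.0370, 0.0369 and 0.0376 FPKM) and Hbb-bs (0.00539, 0.00507 and 0.00508 FPKM) were near 0 in each library, so their values are uncertain. Fibroblast genes passed in no library (-0.06, 0.18 and -0.13). All 8 had a mean of at least 1 FPKM, so that filter removed none of them and left the deviations unchanged. Replicate 3 still passed under it at -0.13, through the random draws and the set of adjusted pairs and not through the members. The adipocyte, lymphocyte, neutrophil and Leydig cell lists also passed in no library, with deviations between -0.08 and 0.08. Most members of these 4 lists had a mean below 1 FPKM, so their medians could hardly move.

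Proliferation genes stood at low levels, and all 9 were lowest in replicate 1. Mki67 stood at 0.355, 2.1 and 2.45 FPKM and Top2a, a topoisomerase of dividing cells, at 0.687, 2.96 and 3.60 FPKM. The list deviated by -0.81, 0.34 and 0.46 (permutation, adjusted p = 0.0012, 0.005 and 0.0021), and by -0.08 and 0.08 in replicates 2 and 3 without replicate 1. With a pseudocount of 0.1 it deviated by -1.28 in replicate 1 and 0.68 in replicate 2, and without replicate 3 by 0.60 in replicate 2. Housekeeping genes deviated by 0.00, -0.03 and 0.10 and passed in no library, with list medians of 9.24, 8.88 and 9.04. Antioxidant, tight junction, luminal acidification, steroid signalling, immediate early and interferon genes passed in none either, with deviations between -0.09 and 0.12. Within the tight junction list, the claudin gene Cldn10 stood at 9.22, 92.5 and 95.0 FPKM and F11r at 63.5 ± 0.115 FPKM (SD, n = 3). Posterior Hox genes also passed in no library, although members of at least 1 FPKM did in replicate 2 (0.57), and Hoxd9 was the highest of them at 47.0 ± 1.67 FPKM (SD, n = 3). Of 7 seminal vesicle genes, 6 were listed at 0 in all libraries and Pate4 stood at 4.45, 1.06 and 0.443 FPKM. The list passed in no library, but Pate4 alone, its only member of at least 1 FPKM, passed in replicates 1 and 3 (1.10 and -0.81).

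**Figure D2:**
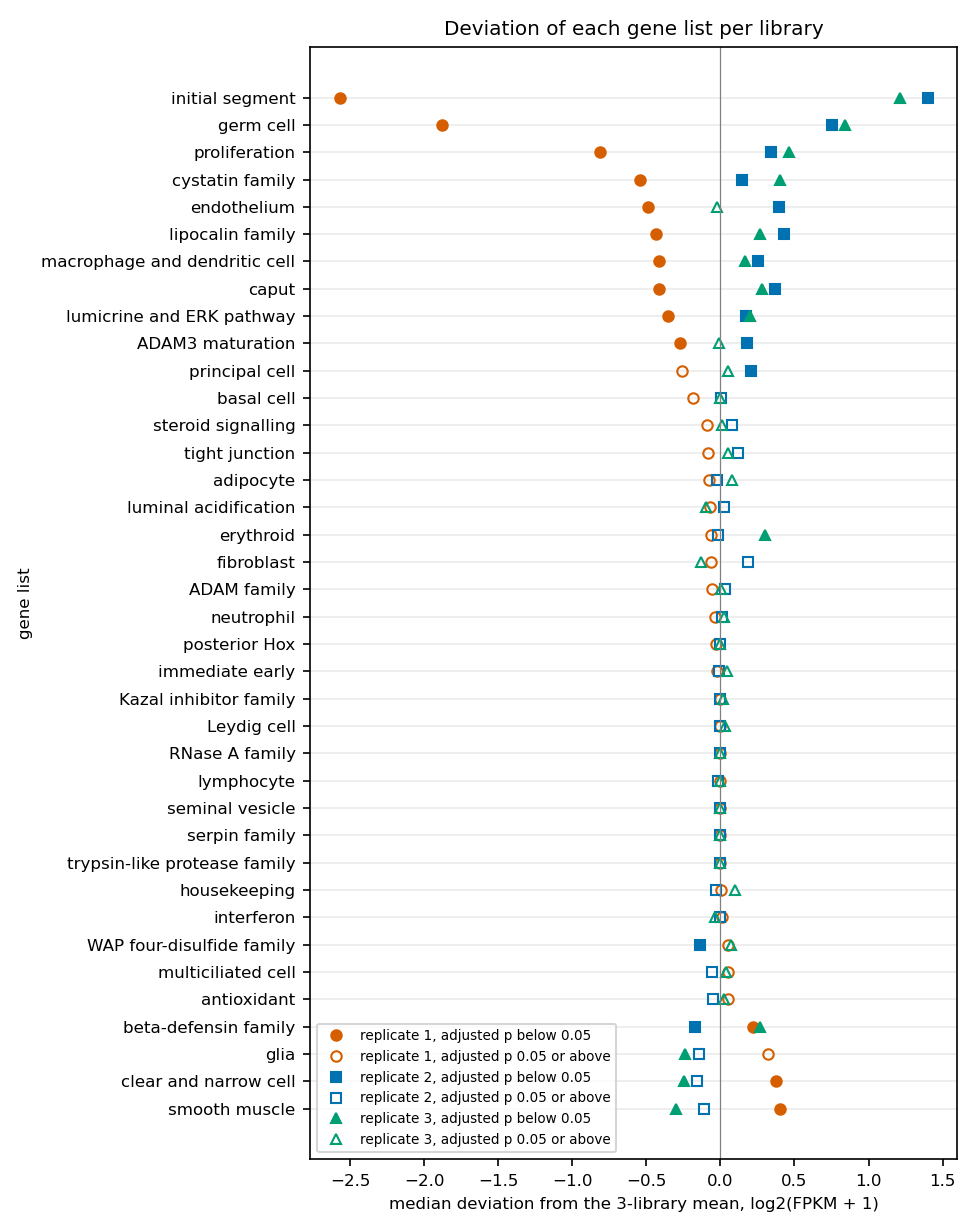
Median deviation of the genes of each of the 38 gene lists (vertical axis), with 1 point per library. Each gene's deviation was taken from that gene's own 3-library mean on the log2(FPKM + 1) scale (horizontal axis). Filled points have an adjusted p below 0.05. The initial segment list lay at -2.57 and the germ cell list at -1.88 in replicate 1, and the housekeeping list near 0 in every library.

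Of the 10 genes of at least 5 FPKM with the widest range, 6 were protein coding. Besides Lcn9, Cst12, Lcn8 and 9230104L09Rik, these were Gm4846, at 0.707, 1930.1 and 1294 FPKM, and 9230110F15Rik, listed at 0 in replicate 1 with 908 and 596 FPKM in replicates 2 and 3. The other 4 were the microRNA genes Mir6385, Mir8104, Mir1668 and Mir6363, each under 200 bases long and listed at 0 in at least 1 library.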

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

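Leaving out genes under 200 bases was chosen after seeing the data; all other alternatives were planned. The Ovch2 level stayed within 1 SD of its mean under every alternative run for it. Leaving out 1 of 3 libraries cannot move a mean that far, whatever the values. The Ovch2 mean was 78.7, 40.9 and 42.4 FPKM without replicates 1, 2 and 3. It was 53.6 FPKM with median-of-ratios scaling and 69.6 FPKM with equal sums. The initial segment minus caput difference stayed negative under every alternative run for it. It was negative in each library, so leaving out a replicate could not change its sign. The count of detected genes, 12945 at 1 FPKM, was 16283 at 0.1 FPKM, 9135 at 5 FPKM and 13417 after rescaling to equal sums, each within 1.5 times. Leaving out each replicate in turn moved the lowest pairwise correlation between 0.965 and 0.989, the count of list and library pairs past the threshold between 12 and 30, and the count of genes varying at least 2-fold between 230 and 1146. The highest correlation and both lowest counts came without replicate 1. With 2 libraries fewer pairs exist and the 2 calls of a list mirror each other. These pair counts are therefore not directly comparable with the count over 3 libraries. With only genes of a mean of at least 1 FPKM the lowest correlation was 0.913, with a mean of at least 5 FPKM 907 genes varied 2-fold, since fewer genes were compared, and without genes under 200 bases the 10 most abundant genes took 17.2% of the total. The causes of the other changes were not tested.

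Of 39 list and library pairs past the threshold, 39 stayed past it under each scaling and without genes under 200 bases, 37 with a pseudocount of 0.1 and 38 with the filter on list members. That filter added 12 pairs, for a total of 50, and the totals were 42 with median-of-ratios scaling, 40 with equal sums, 38 with a pseudocount of 0.1 and 42 without genes under 200 bases. Without replicate 1, of the 26 pairs in replicates 2 and 3, 6 stayed past it, 13 lost it and 7 changed sign. The deviations of 2 libraries are equal and opposite, so a list above the mean in both replicates had to change sign in 1 or lie at 0, and the 7 changes show no instability. Over the settings that leave out 1 replicate, the ranges of the 7 were: initial segment in replicate 3, -0.092 to 1.91; lumicrine and ERK pathway in replicate 3, -0.089 to 0.28; caput in replicate 3, -0.015 to 0.27; macrophage and dendritic cell in replicate 3, -0.053 to 0.30; germ cell in replicate 2, -0.030 to 1.56; proliferation in replicate 2, -0.077 to 0.60; and cystatin family in replicate 2, -0.075 to 0.32. Leaving out replicate 2 ended the beta-defensin calls in replicates 1 and 3, and leaving out replicate 3 ended the WAP call in replicate 2. Over all alternatives, list median levels moved by more than 1 SD in 34 settings of a list and stayed within it in 192, and the named genes' mean FPKM in 9 and 131. Settings that leave out a replicate could only count as within it, since 1 of 3 libraries cannot shift a mean by 1 SD. For those settings the counts are no measure of stability. The authors' comparison planned as an alternative was not run, since no such table was analysed here. No paired analysis was possible because the labels give 1 group. Absolute depth is unknown, so values below 1 FPKM carry no counting interval.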

Other observations

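All tests in this part were chosen after the values were seen, except that of histone genes.

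Outside the 38 lists, 66 genes of at least 1 FPKM lay at least 8-fold below both other libraries in replicate 1, against 5 in replicate 2 and 5 in replicate 3, of which 10, 3 and 5 were listed at 0 there. Genes named here were chosen after their values were seen. No group of them was tested for enrichment. They include the glycosyltransferase genes Gcnt4 (0.261, 61.1 and 50.2 FPKM in replicates 1, 2 and 3), St3gal2 (4.23, 128 and 94.5 FPKM) and St6galnac2 (8.71, 125 and 128 FPKM), the fatty acid elongase gene Elovl4 (0.269, 31.6 and 25.8 FPKM) and Enpp2, which makes lysophosphatidic acid (3.77, 165 and 122 FPKM). The glutamate transporter gene Slc1a1 (5.68, 238 and 202 FPKM) and the potassium channel gene Kcnj11 (0.0259, 18.3 and 20.9 FPKM) were 2 others, as were Zap70 (0.451, 26.5 and 21.3 FPKM), Klrb1c (2.35, 252 and 106 FPKM) and Inpp5d (1.97, 80.7 and 64.1 FPKM). The phosphatase gene Dusp5, a relative of Dusp6, stood at 0.947, 20.5 and 14.8 FPKM.

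Beta-defensin genes of the same cluster differed in the library in which they were low. On chromosome 14, Defb48 (62977524 to 62984510) and Defb47 (62992375 to 63001180) lay at least 2-fold below both other libraries in replicate 1, and Defb30 (63034087 to 63037846) did so in replicate 2. On chromosome 8, 8 genes lay that far below both other libraries in replicate 2 and 1, Defb6, in replicate 1. On chromosome 2 these counts were 5 in replicate 2 and 3 in replicate 1. Outside the family, BC048679 (448, 4.08 and 266 FPKM) and AY761185 (236, 12 and 471 FPKM) were also low in replicate 2. In replicate 3, the neurotensin receptor gene Ntsr2 stood at 288 FPKM, against 1.48 and 0.291 FPKM in replicates 1 and 2.

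Low initial segment genes in replicate 1 were weighed against 3 explanations. Lower depth is argued against by the relative depth of replicate 1, 1.22 times that of replicate 2 and 1.40 times that of replicate 3. Tissue of the initial segment missing from the dissection remains open: Ros1 stood at 0.607 of its lower level in the other libraries, and Rnase9, Rnase13 and Ggt1 were highest in replicate 1, but how far these genes are expressed outside the segment was not measured. A candidate explanation is that no testicular luminal input reached this tissue, since the germ cell list deviated by -1.88. Missing initial segment tissue could also carry fewer sperm, so the germ cell values do not separate these 2, and no biological explanation by genotype was tested because the design has 1 group.

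Ovch2 was lower in replicate 1 than in the other libraries, with a gap of 3.83 on the log2 scale to the nearer one. The criterion for an allele or label of its own was a gap larger than those of the other initial segment genes. Of the 10 others at least 2-fold below both libraries, 8 had a larger gap and 2 a smaller one, so it was not met. An allele or label of its own could also add to a drop shared with these genes, so the rank of the gap cannot decide. An allele or label of its own in replicate 1 therefore remains open, and the reads over each exon were not analysed here.

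Rn45s (324, 3816 and 8568 FPKM), Lars2 (104, 2205 and 5599 FPKM), Rmrp (0.931, 3.40 and 11.7 FPKM) and Rpph1 (2.83, 23.5 and 36.3 FPKM) were lowest in replicate 1 and highest in replicate 3. Rn45s, Rmrp and Rpph1 are transcripts without poly(A) tails, whereas Lars2 encodes a mitochondrial tRNA synthetase. A shared rise of such synthetases is argued against by a median difference of 0.0723 on the log2 scale between replicates 3 and 1 over the 16 others, with 1.07 the largest. More carryover of RNA without poly(A) in replicate 3 than in replicate 2 could not be decided, since the 7 of 68 histone genes with a mean of at least 1 FPKM differed by a median of -0.00353, with quartiles of -0.24 and 0.31. The comparison also assumes that the histone transcripts read here lacked poly(A), which was not measured. Over all 68, most of them near 0, the median was 0, with 14 higher in replicate 3 and 16 in replicate 2. Without more carryover in replicate 3 than in replicate 2, a median at or below 0 was predicted. That was met by less than the spread.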
